A study of Homo sapiens with 6 samples.

How the data were processed

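Small RNA libraries of 6 KPL4 samples, 3 of ERβ knockout cells and 3 of knockout cells with exogenous ERβ, were prepared with a QIAseq miRNA kit for Illumina sequencing, per the labels' protocols, which also name a TaqMan reverse transcription kit. FastQC, Trim Galore and the genome build GRCh38 are named without versions, per the submitters' processing notes. The aligner, the counter, the miRNA annotation release, the rule for reads shared by several miRNAs and any collapsing of unique molecular identifiers are not given in the sources used here. The table deposited by the authors holds expected counts per mature miRNA, of which 6.33 to 7.27% per library are not whole, as where reads are divided among miRNAs. Members of near-identical families can therefore carry part of each other's reads.

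Columns were assigned to groups by their names. Of the knockout columns 2 carry the number 1, another the number 3 and none the number 2; the former are called S1 and S2 after the index that ends their names and are known by group only. All columns were used. Within groups the chi-square per degree of freedom over tested miRNAs was 12.2 or more for every pair, so no pair was as close as counting noise alone.

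Expected counts were rounded to whole numbers, and 3 counts correspond to 0.210 to 0.292 CPM. The groups were compared in R 4.3.3 with edgeR 4.0.16: filterByExpr with its defaults (minimum count 10, minimum total 15), TMM scaling, the robust quasi-likelihood test and Benjamini-Hochberg adjustment over 783 miRNAs at 0.05, in a single fit of all 6 libraries without covariates. These miRNAs held 99.98% of counts, and 269 had an unadjusted p under 0.05. CPM use TMM-scaled totals. The standard error is the fitted log2 fold change over the square root of F. Lists were compared with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, at least 3 tested members). Of 27 lists 23 could be tested and 5 were called, against 0 with an estimated correlation and 16 with fry. Shares of counts, numbers of miRNAs and TMM factors were compared with exact two-sided permutation tests. Figures were drawn with matplotlib 3.10.9.

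The design, the lists, the first set of alternatives and the naming rule were fixed before the data were examined. The rule names the 8 largest rises and 8 largest falls among miRNAs that passed, averaged at least 10 CPM and had no overlap between groups, the 5 most abundant miRNAs, and up to 3 members of each list by smallest adjusted p. miRNAs and clusters outside the rule, such as miR-873-5p and miR-106a-5p, were chosen after their values were seen. Alternatives were 4 other scalings (DESeq2 1.42.0 size factors, upper quartile, totals, TMM without the 10 most abundant), no filter, a filter of 10 CPM in 3 libraries, the DESeq2 test, limma-voom, a fold change threshold, a replicate block, each library left out, and for lists an estimated correlation and fry. Removal of a hairpin GC trend (loess, span 0.75, degree 1) was added after the data were seen. Summing several entries of a mature name was not run, since no name occurs more than once.

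Positions are from GENCODE release 29 on GRCh38. Of the tested miRNAs 768 had an annotated hairpin, found by synonym or by gene symbol, and 690 had exactly 1; 366 were matched both ways, 356 to the same hairpins. Hairpins on the same strand up to 10 kb apart form a cluster. The test was tried on simulated counts of 770 miRNAs: it recovered 10.0% of changes with a true log2 fold change of 0.25, 51.0% at 0.5, 89.8% at 1 and 100% at 2, with 4.62% of calls false (5.88% with DESeq2, 4.69% with voom) and 0 calls when nothing changed. These counts were drawn independently from the fitted model, without a deviating library, shared change within clusters or reads divided among names. The rates hold for such counts and are not error rates of the real calls.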

Results

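Small RNA was sequenced from KPL4 cells, an established human breast adenocarcinoma line, to ask how microRNAs (miRNAs) differ between cells without estrogen receptor β (ERβ, the product of ESR2) and knockout cells that carry exogenous ERβ. One group held 3 libraries of ERβ knockout cells, called S1, S2 and 3 here. The other held 3 libraries with exogenous ERβ, called 1, 2 and 3. Total counts were 11864636, 12228519 and 10618999 in the knockout libraries and 10288413, 14296900 and 14191776 in those with ERβ. Of 2656 mature miRNAs listed, 1864 had a count in at least 1 library and 783 were abundant enough to test. ESR2 messenger RNA is not measured by this assay, so the labels could not be checked on the receptor itself. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples. No other group, such as knockout cells with an empty vector, is among the samples. Whether both groups came from the same knockout clone is not given in the sources used here. For every miRNA below, an effect of ERβ therefore cannot be told apart from other differences between these cells. All log2 fold changes are ERβ over knockout, positive values meaning higher with ERβ, and are given with their standard error and n = 3 per group.

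In the cells with exogenous ERβ, miRNAs of the imprinted 14q32 cluster were higher together: 27 of 34 tested members passed the test and none fell, with a median log2 fold change of 1.09. The pancreas-enriched pair miR-216a-5p and miR-217-5p rose as well, as did miR-100-5p and miR-1246, the last a name that often collects fragments of other RNAs. The miRNAs that fell included miR-146a-5p, a feedback inhibitor of NF-κB signalling, miR-708-5p, the HOX-cluster miRNAs miR-10a-5p and miR-10b-5p, and the cell-cycle inhibitors miR-424-5p, miR-195-5p and miR-497-5p. In all, 77 miRNAs were higher and 104 lower with ERβ by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Of these 181, 58 differed by 2-fold or more, 29 in each direction. In 179 of them every library of one group lay above every library of the other, as in 312 of all tested miRNAs (39.8%, where chance gives 10%).

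The largest rise among miRNAs averaging at least 10 CPM (counts scaled to a common library size) was that of miR-100-5p, of a family that targets mTOR. It went from 3.39 ± 1.12 to 18.7 ± 1.31 CPM (mean ± SD, n = 3 per group), a log2 fold change of 2.48 ± 0.21 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 5.70e-05). Its hairpin lies in an intron of MIR100HG on chromosome 11 (122152229 to 122152308, GRCh38). miR-1246 rose from 17.3 ± 1.08 to 44.2 ± 2.35 CPM (1.35 ± 0.10). miR-216a-5p (1.29 ± 0.12) and miR-217-5p (1.18 ± 0.14), both in introns of MIR217HG on chromosome 2, rose by similar amounts, from 11.5 ± 1.40 to 28.1 ± 1.02 CPM and from 12.1 ± 2.24 to 27.5 ± 0.297 CPM. The remaining 4 of the 8 largest rises all belong to 14q32: miR-411-5p, miR-376c-3p, miR-381-3p and miR-382-5p.

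Of the largest falls, miR-708-5p, in an intron of TENM4 on chromosome 11 (79402022 to 79402109), dropped from 23.4 ± 4.67 to 5.76 ± 0.593 CPM (log2 fold change -2.02 ± 0.18). miR-146a-5p, in an exon of MIR3142HG on chromosome 5 (160485352 to 160485450), fell from 64.5 ± 1.22 to 22.8 ± 1.91 CPM (-1.50 ± 0.10; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.34e-05). miR-767-5p (-1.39 ± 0.12) and miR-105-5p (-1.27 ± 0.10), from neighbouring hairpins in introns of GABRA3 on chromosome X, fell together. miR-10a-5p, in an intron of HOXB3 on chromosome 17 (48579838 to 48579947), was the most abundant of the 8 and went from 4796 ± 572 to 2110 ± 109 CPM (-1.18 ± 0.10). miR-664a-5p (-1.28 ± 0.17), miR-363-3p (-1.11 ± 0.10) and miR-424-5p (-1.09 ± 0.08) were the others.

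**Figure D1:**
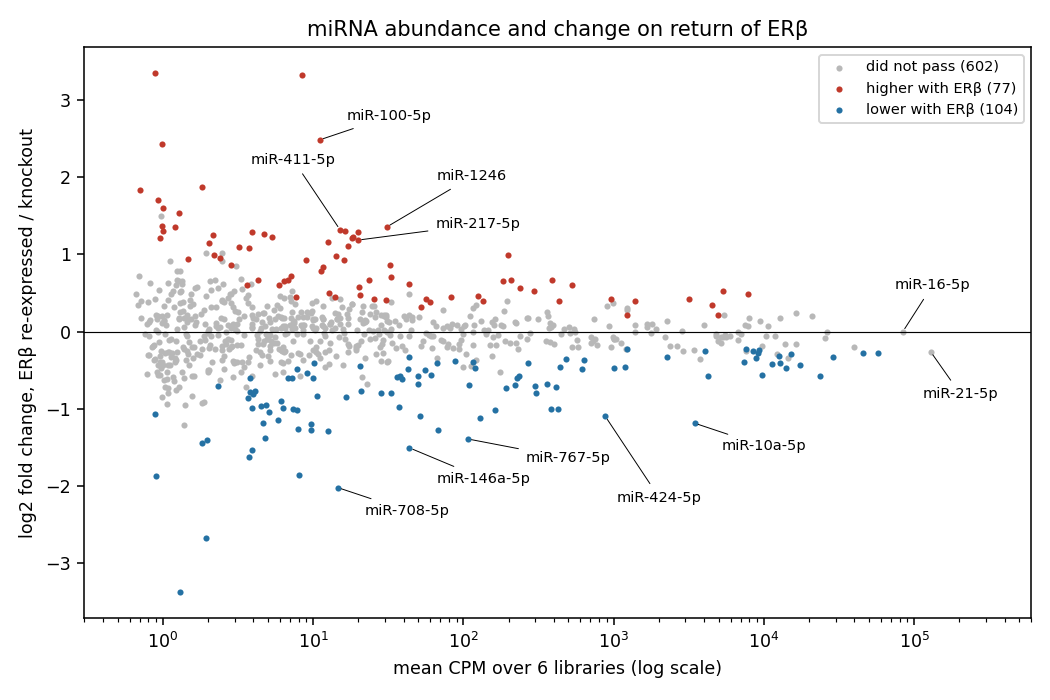
Log2 fold change (ERβ over knockout, 3 libraries each) against mean CPM over the 6 libraries on a log axis, with 1 point per tested miRNA. Red points are the 77 miRNAs higher with ERβ and blue points the 104 lower, a split that turned to 123 and 70 with upper-quartile factors and 146 and 61 with library totals.

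**Figure D2:**
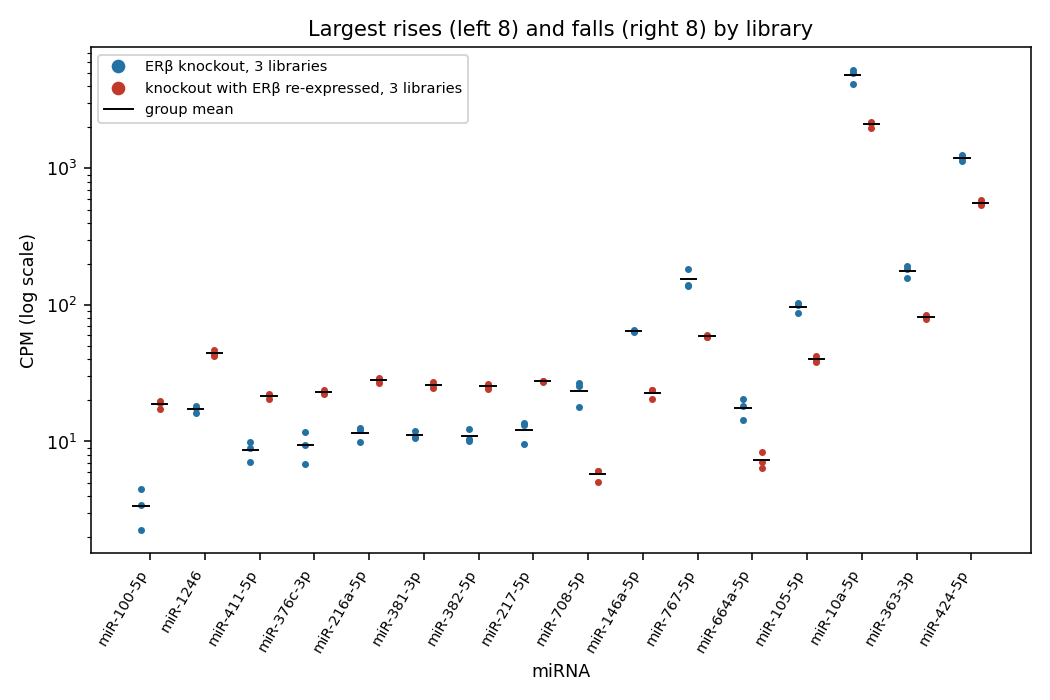
CPM on a log axis of the 8 largest rises and 8 largest falls in each of the 6 libraries, with a bar at each group's mean. Knockout libraries are blue and libraries with ERβ red; miR-100-5p goes from a mean of 3.39 to 18.7 CPM.

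The 14q32 list held miRNAs of the DLK1-DIO3 region, which are expressed from the maternal chromosome. Adjusted over the list alone, 32 of its 34 tested members were higher. miR-381-3p rose from 11.1 ± 0.783 to 25.8 ± 1.29 CPM (1.22 ± 0.12), with miR-382-5p at 1.21 ± 0.12, miR-411-5p at 1.32 ± 0.14 and miR-376c-3p at 1.30 ± 0.18. The tested miRNAs with a single hairpin in the annotated cluster lie between 101022066 and 101065667 on chromosome 14; 25 of these 31 rose. Camera, a competitive list test with a preset correlation of 0.01, gave an adjusted p of 8.22e-19; the list had an adjusted p = 0.249 with an estimated correlation, and 2.10e-20 to 1.01e-08 over the other alternatives of camera; fry, which tests a list against no change and not against other miRNAs, gave an adjusted p of 0.00139. Beside this rise, markers of stromal, endothelial, muscle, blood, neural and liver cells had a median log2 fold change of -0.40 over 21 tested, with 0 higher and 10 lower. Some were abundant in these libraries, such as miR-9-3p at 9962 ± 1028 CPM in knockout cells. The 14 markers under 100 CPM in knockout cells had a median of -0.42 (95% interval -1.09 to 0.02). The markers therefore do not decide whether other cells were present.

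**Figure D3:**
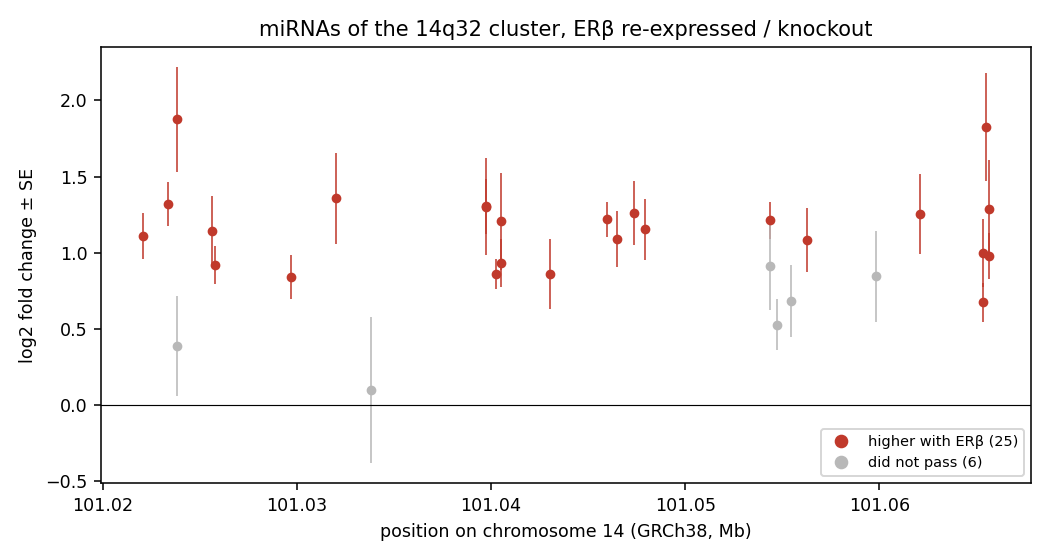
Log2 fold change with its standard error (bars) of 31 miRNAs with 1 hairpin in the 14q32 cluster against hairpin position on chromosome 14 (GRCh38). Red points passed the test as higher with ERβ and grey points did not (6); values run from 0.10 to 1.88.

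Camera called 4 lists lower. Of miRNAs tied to endoplasmic reticulum stress, 5 of 10 were lower, 6 adjusted over the list alone (median -0.73; camera adjusted p = 0.00594, and adjusted p = 0.281 with an estimated correlation, and 2.27e-05 to 0.0560 over the other alternatives of camera; fry adjusted p = 6.03e-04). The call was lost under the filter of 10 CPM in 3 libraries, and the list had 0 higher and 3 lower without ERβ library 1. Beside miR-708-5p, which the stress factor CHOP induces, miR-424-5p fell from 1196 ± 60.2 to 560 ± 26.7 CPM and miR-503-5p by a log2 fold change of -0.68 ± 0.13. Of the 5 lower members, miR-424-5p, miR-424-3p and miR-503-5p come from the same X-linked cluster and also belong to the miR-15/16 family. The list gives no direction for its members, so their falls do not give the direction of a stress response. The stromal and endothelial list had 5 of 7 lower, 5 adjusted over the list alone (median -0.69; camera adjusted p = 0.00254, and adjusted p = 0.425 with an estimated correlation, and 7.74e-04 to 0.0364 over the other alternatives of camera; fry adjusted p = 0.00430). miR-199b-5p fell from 388 ± 41.9 to 223 ± 10.3 CPM (-0.80 ± 0.10), and miR-143-3p by a log2 fold change of -1.15 ± 0.15. miR-199a-3p (-0.69 ± 0.09) and miR-199b-3p have the same mature sequence, so the same reads are divided between these names and the 5 lower members include both.

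The miR-23, miR-27 and miR-24 clusters had 4 of 9 lower, 5 adjusted over the list alone (median -0.24; camera adjusted p = 0.0370, and adjusted p = 0.355 with an estimated correlation, and 0.00907 to 0.0936 over the other alternatives of camera; fry adjusted p = 0.00175). miR-23b-3p (-0.58 ± 0.06) and miR-27b-3p (-0.43 ± 0.07), both in introns of C9orf3, fell with miR-24-3p (-0.39 ± 0.07). The NF-κB and inflammation list had 4 of 15 lower, 5 adjusted over the list alone (median -0.25; camera adjusted p = 0.0431, and adjusted p = 0.409 with an estimated correlation, and 0.00961 to 0.101 over the other alternatives of camera; fry adjusted p = 0.00267). With miR-146a-5p fell its paralog miR-146b-5p, from 240 ± 3.43 to 145 ± 3.14 CPM (-0.73 ± 0.08), and miR-9-3p (-0.28 ± 0.08). miR-146b-5p kept its call in every alternative, while miR-9-3p lost it in 10 of 16 and miR-24-3p in 1 of 16. Both lists lost the call with upper-quartile factors (camera adjusted p = 0.0831 for each) and with library totals (0.0936). The inflammation list had 0 higher and 2 lower and 1 higher and 2 lower under these scalings, and the miR-23, miR-27 and miR-24 clusters 0 higher and 2 lower with library totals. Both also lost it without knockout library S1 (0.0892 and 0.101), knockout library 3 (0.0692 and 0.0748), ERβ library 1 (0.0598 for each) or ERβ library 2 (0.0908 and 0.0778). The inflammation list lost it further without ERβ library 3 (0.0702), without a filter (0.0691) and with the filter of 10 CPM in 3 libraries (0.0560); it had 0 higher and 9 lower without knockout library S2, and 0 higher and 2 lower without knockout library S1, knockout library 3, ERβ library 1, ERβ library 2 or ERβ library 3.

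In the miR-15/16 family, which restrains cyclins and BCL2, 6 of 15 were lower and none higher, also adjusted over the list alone (camera adjusted p = 0.0614; 0.0272 and called without a filter, 0.0272 to 0.0946 over its camera alternatives with the preset correlation, and adjusted p = 0.355 with an estimated correlation), against 1 higher and 5 lower with upper-quartile factors and 2 higher and 5 lower with library totals. miR-195-5p fell from 510 ± 16.9 to 254 ± 5.61 CPM and miR-497-5p by a log2 fold change of -0.72 ± 0.07 along with miR-424-5p, while the far more abundant miR-16-5p did not pass (-0.00 ± 0.06). The miR-17 family clusters moved both ways, 4 of 22 higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.493), and 6 higher and 3 lower with upper-quartile factors and 10 higher and 3 lower with library totals. miR-18a-5p rose from 159 ± 27.5 to 252 ± 8.23 CPM (0.67 ± 0.13); miR-20b-5p, from 570 ± 32.6 to 284 ± 4.67 CPM, and miR-363-3p, both of the X-linked paralogous cluster, fell. These clusters had 9 higher and 4 lower without knockout library S2, and 1 higher and 3 lower without ERβ library 1, ERβ library 2 or ERβ library 3.

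Of miRNAs enriched in luminal breast cancer 4 of 17 were lower, also adjusted over the list alone (camera adjusted p = 0.245), against 1 higher and 4 lower and 2 higher and 3 lower with upper-quartile factors and library totals. miR-449a fell from 49.1 ± 5.80 to 25.1 ± 1.62 CPM (-0.97 ± 0.12), with miR-375-3p at -0.57 ± 0.10 and miR-26a-5p at -0.40 ± 0.08. Among miRNAs that target ESR1, the gene of ERα, 1 of 10 was higher and 3 lower, 1 and 6 adjusted over the list alone (camera adjusted p = 0.384), and 2 higher and 1 lower with library totals. miR-22-3p (-0.46 ± 0.07) and miR-222-3p (-0.37 ± 0.07) fell and miR-18a-5p rose. The cluster of miR-221 and miR-222 had 2 of 4 lower, 4 adjusted over the list alone (camera adjusted p = 0.0703), 1 with upper-quartile factors and 0 with library totals; miR-221-3p was at -0.34 ± 0.08 and miR-221-5p, which did not pass, at -0.29 ± 0.11. miR-222-3p lost its call in 2 of 18 alternatives and miR-221-3p in 6 of 18. The p53-induced list had 1 of 12 higher, miR-192-5p (0.21 ± 0.07), and 2 lower, miR-143-3p and miR-34c-5p (-0.49 ± 0.12), also adjusted over the list alone (camera adjusted p = 0.493). Its median of -0.07 turned to 0.04 with upper-quartile factors and 0.08 with library totals. With a library left out the luminal list had 0 higher and 7 lower without knockout library S2; the ESR1-targeting list had 1 higher and 6 lower without knockout library S2, and 1 higher and 1 lower without ERβ library 2. The cluster of miR-221 and miR-222 had 0 higher and 4 lower without knockout library S2, 0 higher and 1 lower without knockout library S1, ERβ library 1 or ERβ library 3, and 0 higher and 0 lower without ERβ library 2; camera called it without knockout library S2 (adjusted p = 0.0306, 0.0306 to 0.152 over its camera alternatives with the preset correlation, and adjusted p = 0.388 with an estimated correlation). miR-192-5p lost its call in 10 of 18 alternatives and miR-34c-5p in 5 of 18. For the p53-induced list the counts were 2 higher and 3 lower without knockout library S2, and 0 higher and 1 lower without knockout library S1, knockout library 3, ERβ library 1, ERβ library 2 or ERβ library 3.

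Of the metastasis-suppressing list 1 of 15 was higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.493), against 5 higher and 3 lower with upper-quartile factors and with library totals alike; miR-708-5p and the miR-146 pair led the falls. The pro-metastatic list had 2 of 14 higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.898), against 3 higher and 1 lower under both of those scalings. miR-10b-5p, in an intron of HOXD3, fell from 12.6 ± 1.16 to 3.46 ± 0.258 CPM (-1.85 ± 0.15) and miR-183-3p rose (0.32 ± 0.10). The cluster of miR-183, miR-96 and miR-182 had 2 of 6 higher, also adjusted over the list alone (camera adjusted p = 0.111), with miR-183-5p at 0.22 ± 0.07 and miR-182-5p, which did not pass, at 0.17 ± 0.07. miR-183-3p lost its call in 9 of 18 alternatives and miR-183-5p in 7 of 18. This cluster had 0 higher and 0 lower without knockout library S1, knockout library 3, ERβ library 1, ERβ library 2 or ERβ library 3. The metastasis-suppressing list had 3 higher and 6 lower without knockout library S2, and 2 higher and 5 lower without knockout library 3, and the pro-metastatic list 4 higher and 5 lower without knockout library S2, and 0 higher and 1 lower without knockout library S1, knockout library 3, ERβ library 1, ERβ library 2 or ERβ library 3.

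The let-7 family had 4 of 19 lower, 5 adjusted over the list alone (camera adjusted p = 0.186), against 1 higher and 0 lower with upper-quartile factors or library totals. let-7a-5p was at -0.28 ± 0.06, let-7f-5p at -0.27 ± 0.07 and let-7d-5p at -0.25 ± 0.07. These calls were lost in 5 of 16, 8 of 16 and 8 of 18 alternatives. The let-7 counts were 0 higher and 9 lower without knockout library S2, 0 higher and 2 lower without knockout library S1, and 0 higher and 0 lower without ERβ library 1, ERβ library 2 or ERβ library 3. The miR-200 family, which maintains E-cadherin, had 2 of 9 lower, also adjusted over the list alone (camera adjusted p = 0.711), against 1 higher and 0 lower with upper-quartile factors and 2 higher and 0 lower with library totals. Its lower members were miR-200c-3p (-0.31 ± 0.07) and miR-141-3p (-0.33 ± 0.09), and miR-200b-3p did not pass (-0.25 ± 0.09). miR-200c-3p lost its call in 5 of 18 alternatives and miR-141-3p in 9 of 18. With a library left out the miR-200 family had 2 higher and 4 lower without knockout library S2, 0 higher and 1 lower without knockout library S1 or knockout library 3, and 0 higher and 0 lower without ERβ library 1, ERβ library 2 or ERβ library 3. In the miR-30 family 2 of 11 were lower, also adjusted over the list alone (camera adjusted p = 0.423), namely miR-30d-5p (-0.57 ± 0.10) and miR-30b-5p (-0.33 ± 0.08), against 1 higher and 1 lower with upper-quartile factors or library totals; miR-30c-5p was at -0.19 ± 0.07. miR-30b-5p lost its call in 7 of 18 alternatives. The miR-30 counts were 0 higher and 5 lower without knockout library S2, and 0 higher and 1 lower without knockout library S1, knockout library 3, ERβ library 1, ERβ library 2 or ERβ library 3.

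None of 7 miR-29 members passed, nor adjusted over the list alone (camera adjusted p = 0.833), and 1 was higher with upper-quartile factors and 2 with library totals; miR-29a-3p was at 0.13 ± 0.06, miR-29c-5p at -0.22 ± 0.09 and miR-29c-3p at -0.18 ± 0.09. In the clusters of miR-99, miR-100 and miR-125 only miR-100-5p passed, 1 of 9, also adjusted over the list alone (camera adjusted p = 0.924, direction down). The median of this list was -0.12 and its mean 0.17, and the median turned to 0.04 with library totals. miR-125b-5p, with 1 of its hairpins in the same host gene MIR100HG, was at -0.25 ± 0.11 and miR-125a-5p at -0.29 ± 0.13; neither passed. The hypoxia list had 2 of 11 lower, miR-24-3p and miR-26a-5p, also adjusted over the list alone (camera adjusted p = 0.840, direction down), against 1 higher and 1 lower with library totals. Its median was 0.03 and its mean -0.06, with miR-26a-1-3p at 0.14 ± 0.09. The median of the hypoxia list turned to -0.00435 without knockout library 3. The miR-29 family had 1 higher and 2 lower without knockout library S2, the clusters of miR-99, miR-100 and miR-125 3 higher and 2 lower without knockout library S2, and the hypoxia list 1 higher and 2 lower without knockout library S2.

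Of the muscle markers 2 of 2 were lower, also adjusted over the list alone: miR-1-3p from 3.35 ± 0.528 to 0.515 ± 0.233 CPM (-2.67 ± 0.33) and miR-499a-5p (-0.98 ± 0.14). The neural and liver list had 3 of 8 lower, also adjusted over the list alone (camera adjusted p = 0.209), led by miR-338-3p (-1.09 ± 0.11) and miR-129-5p (-0.45 ± 0.13), against 1 higher and 1 lower with library totals. It had 0 higher and 1 lower with upper-quartile factors, and miR-129-5p lost its call in 8 of 16 alternatives. No blood cell marker passed, 0 of 4, nor adjusted over the list alone (camera adjusted p = 0.560): miR-451a was at -0.80 ± 0.29, miR-144-5p at -0.20 ± 0.37 and miR-142-3p at 0.02 ± 0.18, and the median of -0.10 turned to 0.01 with upper-quartile factors and 0.05 with library totals. The blood cell median was also positive without knockout library 3 (0.080), without ERβ library 1 (0.048) and with DESeq2 (0.0054), each with 5 tested. No pluripotent cell marker was abundant enough to test. Names that often collect fragments of other RNAs had 2 of 7 higher, also adjusted over the list alone (camera adjusted p = 0.825, direction up): miR-1246 and miR-1290 (1.23 ± 0.17). Their median was -0.29 and their mean 0.13, with miR-1260b at -0.38 ± 0.15. Without a filter the median of these names was 0.045 over 15 members. The placental C19MC cluster had 1 testable member, miR-516a-5p (0.16 ± 0.54), and the ERBB2 amplicon 2, miR-4728-5p (0.20 ± 0.31) and miR-4728-3p (0.10 ± 0.28). None of these passed, over all miRNAs or adjusted over the list alone. With a library left out the ERBB2 amplicon had 1 higher and 0 lower without knockout library S2, the fragment-like names 2 higher and 1 lower without knockout library S2 or knockout library 3, and the neural and liver list 0 higher and 5 lower without knockout library S2, and 0 higher and 1 lower without knockout library S1, ERβ library 1, ERβ library 2 or ERβ library 3.

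The most abundant miRNA, miR-21-5p, went from 140072 ± 29747 to 117060 ± 1607 CPM and did not pass (-0.26 ± 0.14; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.214), nor did miR-9-5p (-0.19 ± 0.08; adjusted p = 0.110 in the same test). Without knockout library S2 both passed in that edgeR quasi-likelihood test with Benjamini-Hochberg adjustment: miR-21-5p at -0.42 ± 0.04 (adjusted p = 4.67e-09, 4.67e-09 to 0.590 over the alternatives) and miR-9-5p at -0.27 ± 0.04 (adjusted p = 5.77e-06, 5.77e-06 to 0.704 over the alternatives). The top miRNA took 13.2 ± 2.37% of counts in knockout libraries and 12.4 ± 0.108% with ERβ (exact two-sided permutation test, p = 0.4, n = 3 per group). For the 10 most abundant the shares were 48.7 ± 1.87% and 47.5 ± 0.349% (exact permutation p = 0.4), and the number of miRNAs with at least 10 counts was 759 ± 40.4 and 798 ± 32.5 (exact permutation p = 0.2). Library S2 was low in both shares, at 10.5% and 46.5%, and without it the difference in the share of the 10 most abundant went from -1.22 to -2.30 points. It was -0.746 without knockout library S1, -0.627 without knockout library 3 and -0.702 with the most abundant miRNA left out. The smallest p these exact tests allow with 3 against 3 is 0.1.

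The median fold change moved by 0.11 with upper-quartile factors and 0.15 with library totals, where 123 were higher and 70 lower, and 146 higher and 61 lower. Knockout library S2 stood apart from the other knockout libraries; without it 279 miRNAs passed (122 higher, 157 lower), and without ERβ library 1, 2 or 3 the count was 111, 112 or 111.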

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

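Each count below was recomputed under the alternatives, and the cause of a difference was not tested unless the alternative itself sets it. The number of changed miRNAs, 181, with a library left out ran from 111 without ERβ library 1 or 3 to 279 without knockout library S2, and over the same left-out libraries the higher ones ran from 49 to 122 and the lower ones from 58 to 157. Upper-quartile factors gave 123 higher, library totals 146 higher and 61 lower, the filter of 10 CPM in 3 libraries 66 lower, and a log2 fold change of at least 1, by construction, 58 changed, 29 higher and 29 lower. The 5 lists became 3 with upper-quartile factors, with library totals and with the stricter filter, 0 with an estimated correlation and 16 with fry, and 3 to 6 with a library left out. Changed miRNAs numbered 162 with DESeq2, 193 with voom, 203 without a filter, and 166 with the GC trend removed against 154 over the same miRNAs. Single miRNAs were recomputed for 78, those of the naming rule and some chosen after their values were seen. Of these 58 had passed. Among the 58, 40 passed in every alternative run for them, 18 lost the call in some and 0 changed sign. miR-196a-5p, miR-196b-5p, miR-424-3p and miR-199b-3p were not recomputed in this way.

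Lists with higher and lower members moved by over 1.5 times were, without a filter, let-7 0 and 2, miR-17 7 and 3, p53-induced 0 and 2, pro-metastatic 1 and 1, metastasis-suppressing 3 and 5, miR-183 1 and 0, inflammation 0 and 2, endoplasmic reticulum stress 0 and 8, fragment-like 2 and 1, neural and liver 0 and 1. With the stricter filter they were miR-15/16 1 and 5, p53-induced 1 and 1, pro-metastatic 3 and 1, metastasis-suppressing 2 and 4, miR-29 1 and 0, inflammation 0 and 2, 14q32 13 and 0, fragment-like 1 and 0, neural and liver 0 and 1. That filter left only 13 members of 14q32 to test, and all 13 were higher (median log2 fold change 1.02). TMM without the 10 most abundant and DESeq2 each gave p53-induced 0 and 2, pro-metastatic 1 and 2, miR-183 1 and 0, and DESeq2 also fragment-like 2 and 1. Over miRNAs with 1 hairpin, which leaves members out, 6 lists had lower members reduced by over 1.5 times; removal of the GC trend among these gave miR-200 1 and 1, miR-17 7 and 3, metastasis-suppressing 2 and 4, blood cell 0 and 1.

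With the replicate number as a block, the count of changed miRNAs was 158 with S1 taken as 1 and S2 as 2, and 186 the other way round, with 3 lists called in each blocked fit, the miR-23 and inflammation lists not among them. Deviations from the group means correlated at -0.0957, -0.0349 and 0.123 between libraries of the same number when S1 is 1, and at 0.134, 0.0833 and 0.123 when S2 is 1. In the latter numbering every library correlated best with the library of its own number, a hint from the data and not from the design. Since S1 and S2 carry no number of their own and not every value exceeded 0.1, whether the numbers mark paired samples stays open, and the block was not used elsewhere. The lists moved by over 1.5 times were, with S1 as 1, miR-200 0 and 1, let-7 0 and 2, p53-induced 0 and 2, pro-metastatic 0 and 1, miR-183 0 and 0, inflammation 0 and 2; with S2 as 1, p53-induced 0 and 2, pro-metastatic 1 and 2, metastasis-suppressing 2 and 4, miR-183 1 and 0.

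Among the 78 miRNAs recomputed, signs turned only in some that had not passed. The log2 fold change of miR-16-5p, -0.00428, became 0.00394 with DESeq2 factors, 0.107 with upper-quartile factors, 0.150 with totals, 0.0433 without a filter, 0.0374 with the stricter filter and 0.00139 with DESeq2, and ran from -0.0234 to 0.0591 with a library left out. With the GC trend removed miR-29a-3p was at -0.0270 and miR-142-3p at -0.0121. With a library left out miR-142-3p ran from -0.155 to 0.177, miR-516a-5p from -0.316 to 1.01, miR-4728-3p from -0.0929 to 0.556 and miR-144-5p from -0.484 to 0.268. Summing entries of the same mature name was not run, since no name occurs more than once.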

Other observations

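The clusters and miRNAs in this paragraph were chosen after their values were seen. The X-linked cluster of MIR424, MIR450A, MIR450B, MIR503 and MIR542 had 8 of 10 tested miRNAs lower with ERβ (median log2 fold change -0.61) and MIR195 with MIR497 on chromosome 17 3 of 4 (-0.66). These hold the falling members of the miR-15/16 family, while MIR15A with MIR16-1 and MIR15B with MIR16-2 had none called. MIR489 and MIR653 had 3 of 3 lower, and MIR449A, MIR449B and MIR449C 2 of 3. MIR216A with MIR217 had 3 of 3 higher and MIR374A with MIR545 3 of 4. The scarce miR-873-5p had the log2 fold change 3.32 ± 0.23, from 1.55 ± 0.556 to 15.3 ± 1.31 CPM. miR-10a-5p and miR-10b-5p fell while miR-196a-5p (-0.08 ± 0.09) and miR-196b-5p (0.05 ± 0.14), which also lie in HOX clusters, did not pass.

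Exploratory tests of neighbouring hairpins and of miR-106a-5p were chosen after the results were seen. Over 38 clusters the variance of fold changes within clusters was 0.0472 against 0.353 in shuffled hairpins, and without 14q32 0.0457 against 0.304 (permutation p = 0.001, the smallest the shuffles allow). The shuffles drew on all hairpins with a fold change, also those outside clusters, and 120 hairpins lay in clusters. A narrower spread of clustered hairpins would give the same result, so the shuffles alone cannot decide whether neighbours change together. Without 14q32, cluster medians ran from -1.003 (MIR106A, MIR18B, MIR20B and MIR363) to 1.29 (MIR216A with MIR217). Between them lay MIR195 with MIR497 at -0.66 and MIR374A with MIR545 at 0.426. Beside the variance of 0.0457 within clusters, this range argues against a narrow spread as the whole explanation. Some clusters had medians near 0, and members of the MIR106A cluster ran from -1.11 to 0.445. miR-106a-5p rose (0.45 ± 0.12, the call lost in 3 of 18 alternatives) while miR-106a-3p (-1.04 ± 0.20), miR-20b-5p and miR-363-3p of its cluster fell. It differed from miR-17-5p by 0.05 (combined SE 0.17) and made up 17.6 to 19.8% of its counts in every library; this is in line with reads of miR-17-5p counted under miR-106a-5p, and the rule for shared reads that would settle it is not given in the sources used here.

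For the rise of 14q32, the tests on markers, on scaling and on GC were chosen after the result was seen. A pooled test of markers of other cell types came first and left the question open: the 21 markers had a median of -0.40 (95% interval -0.80 to -0.09), but the 14 under 100 CPM in knockout cells had -0.42 (-1.09 to 0.02). The test was split by cell type only after that. Stromal, endothelial and muscle markers had a median of -0.69 (-1.15 to -0.30), with 0 of 9 higher and 7 lower. Blood, neural and liver markers had -0.20 (-0.57 to 0.02), which leaves those cells open. The intervals treat markers as independent, though miR-199a-3p and miR-199b-3p share reads and the stromal and endothelial list had an estimated correlation of 0.690. The intervals are therefore too narrow to decide on stromal, endothelial or muscle cells. The lowest median of 14q32 under another scaling was 1.08. These scalings shifted fold changes by a median of only -0.00453 to 0.154, so none of them could have removed the rise. This shows only that the choice among them does not make the rise. The lower of the medians with the GC trend removed and without library S2 was 0.99, which argues against S2 as the source of the rise. Whether ERβ acts on the cluster or the cells that received ERβ differed in its imprinting beforehand stays open.

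For library S2 all tests were chosen after the result was seen. Its chi-square per degree of freedom was 307 and 331 against the other knockout libraries, which had 14.8 between them, and 313 to 399 against the ERβ libraries, to which S1 and 3 had 204 to 253, so this measure alone does not place S2 in its group. Its deviation from S1 and 3 correlated with hairpin GC at 0.422 over 690 miRNAs (0.0624 for S1 against 3), or 17.8% of its variance. This GC content is that of the whole hairpin and not of the mature miRNA that was sequenced. A GC effect on the reads of S2 was therefore not measured. A swap with a library of the other group is argued against by its lowest correlation within its group exceeding its highest outside by 0.00651 and by a chi-square of 12.2 to 21.2 among the ERβ libraries, none of which lay nearer to a knockout library, and depth by a total of 12.2 M counts, inside the range of the others. A culture difference stays open.

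The tests over regroupings were set before the results were seen. Splitting the 6 libraries into 3 and 3 gave 181 changed miRNAs for the real groups and 0 as the highest of the other splits, and 5 lists against 2. Only 1 of 10 splits reached each real value, and the splits are too few for a share under 0.05. Every other split mixes libraries of both real groups, so any group difference adds to the spread within each side and lowers the calls. The value of 0 therefore does not measure how many calls chance gives.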
